A study of Homo sapiens with 6 samples.

How the data were processed

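The data are RNA-seq counts from 6 libraries of UM-Chor1 chordoma cells, 2 biological replicates each for the guides sg-EGFP, sg-T_1 and sg-T_2. Per the labels' protocols, cells were infected with lentivirus carrying Cas9 and a guide in 4 µg/mL polybrene, selected in 2 µg/mL puromycin, and harvested 2 days after return to growth medium. Libraries were made with a directional kit and sequenced as paired reads of 100 bp. The labels do not say whether the replicates came from separate infections, so the p-values measure the spread between these libraries, which may be in part technical. Groups and replicate numbers were taken from the sample titles.

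The authors deposited 1 table of raw read counts per gene, with 60498 genes and 4 entries that name no gene (unmapped, multimapping, no feature, ambiguous). Per the submitters' processing notes, Trim Galore 0.4.1, STAR 2.4.2 and the build GRCh38 were used. The annotation release and the strand setting of the counting are not given in the sources used here. Overlapping genes on opposite strands, near-identical paralogs and pseudogenes can therefore hold reads of one another. They can also lack reads that were set aside as ambiguous or multimapping. The table does not resolve either. Overlaps were looked up only for genes under the naming rule. Besides those the report points out, BASP1, CHRD, FOXA1, WNT5B, FOXC2, DLL1, GAD1, KRT7, TNC, DTL, PPM1D, OAS1, CTGF, IER3, EPHA4, SLC2A1, SLC7A11, ACAT2, RRP12, CCNC and FGF1 overlap a gene on the other strand, and their values are uncertain in the same way. The 4 entries without a gene held 23.7% to 28.8% of the reads listed per library and were left out of library sizes and tests. Gene names and positions came from GENCODE 29 on GRCh38, in which 56868 of the 60498 identifiers were found, and the unmatched ones held 0.039% of counts.

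Counts assigned to genes ranged from 17187785 to 27337149 per library. A count of 0 allows up to 3 counts, or 0.110 to 0.175 CPM in a library, for counting error only. The libraries had no molecular identifiers, so counts and intervals are not of independent molecules. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom of 15.9 for sg-EGFP, 21.9 for sg-T_1 and 6.30 for sg-T_2, which library preparation and amplification alone can also give. They were taken as biological replicates from the labels.

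From the deposited counts, edgeR 4.0.16 in R 4.3.3 kept 17250 genes with filterByExpr at its minimum count of 10, scaled libraries by TMM and fitted a robust quasi-likelihood model of the 3 groups (common biological coefficient of variation 0.104, 3 residual degrees of freedom). The scaling factors ranged from 0.983 to 1.06. CPM values are scaled by TMM. Contrasts compared the mean of both sg-T guides with sg-EGFP, each guide with sg-EGFP, and sg-T_1 with sg-T_2. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors were taken as the log2 fold change divided by the square root of F. A total of 24 gene lists with 640 entries were fixed before the data were examined, as were the tests and the rule for named genes, and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. All 640 entries matched an identifier.

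Named genes are TBXT, and the 10 highest and 10 lowest log2 fold changes over both guides among genes with a symbol, a mean of at least 5 CPM, an adjusted p under 0.05 in that contrast and in each guide, and the same direction. For the other 3 comparisons they are the 5 highest and 5 lowest with the same minimum CPM and an adjusted p under 0.05. For each list they are up to 2 higher and 2 lower members with the smallest adjusted p. Other list members that the text names were chosen after their values were seen: SOX9, KRT8, KRT19, SHH, NOG, CD24, COL9A3, MATN3, MKI67, CDKN1A, EGFR, TGFBI, LIF, COL1A2, COL3A1, DCN, LUM and FN1. A few genes under the rule are not reported here. The genes of chromosome 6 in the closing section were chosen in the same way.

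The fit was tested on simulated data in which 200 of 17250 genes were changed. For both guides against sg-EGFP, edgeR recovered 41.2% of genes changed by 0.5 on the log2 scale, 80.3% of those changed by 1 and 97.0% of those changed by 2, with 10 false calls among 155. For sg-T_1 against sg-T_2 it recovered 23.5%, 60.6% and 87.9%. Shared controls were checked with 40 simulated sets of unchanged groups. Alternatives chosen before the data were examined were DESeq2's size factors, library totals, no filter on low counts, a minimum of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, fits of only the groups compared, the 4 sg-T libraries as 1 group, and controls divided between the guides. Leaving out the mitochondrial genome and testing against a 1.5-fold change were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. Guide sequences, cut positions and protein levels were not analysed here.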

Results

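RNA was sequenced from UM-Chor1 cells, an established line from a human chordoma, a bone tumour of the axial skeleton that carries features of the embryonic notochord. The cells had received a lentivirus with Cas9 and 1 guide RNA. The guides sg-T_1 and sg-T_2 were directed at T (TBXT), which encodes brachyury, the T-box transcription factor that marks the notochord. The control guide sg-EGFP was directed at a gene of jellyfish origin that the human genome does not hold. Each of the 3 groups had 2 biological replicates, giving 6 libraries, and cells were harvested 2 days after puromycin had been replaced by growth medium. Counts assigned to genes totalled 22889941 and 27337149 for the sg-EGFP replicates, 21835521 and 21910938 for sg-T_1, and 25317631 and 17187785 for sg-T_2. The comparisons address which transcripts of chordoma cells change when brachyury is targeted, and whether both guides give the same changes.

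TBXT itself was measured first. Its gene lies on chromosome 6, positions 166157656 to 166168700 of GRCh38, on the minus strand (ENSG00000164458). TBXT stood at 1198 ± 167 CPM (SD, n = 2) with sg-EGFP, 293 ± 70.9 CPM with sg-T_1 and 309 ± 27.7 CPM with sg-T_2. It fell by 2.03 on the log2 scale with sg-T_1 and by 1.95 with sg-T_2, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 4.4e-16 and 2.8e-15. The log2 difference between the guides was -0.08 ± 0.15 (SE), with adjusted p = 1 in the same edgeR test. Where in the gene each guide cuts is not given in the sources used here, and transcript levels do not measure the protein.

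**Figure D1:**
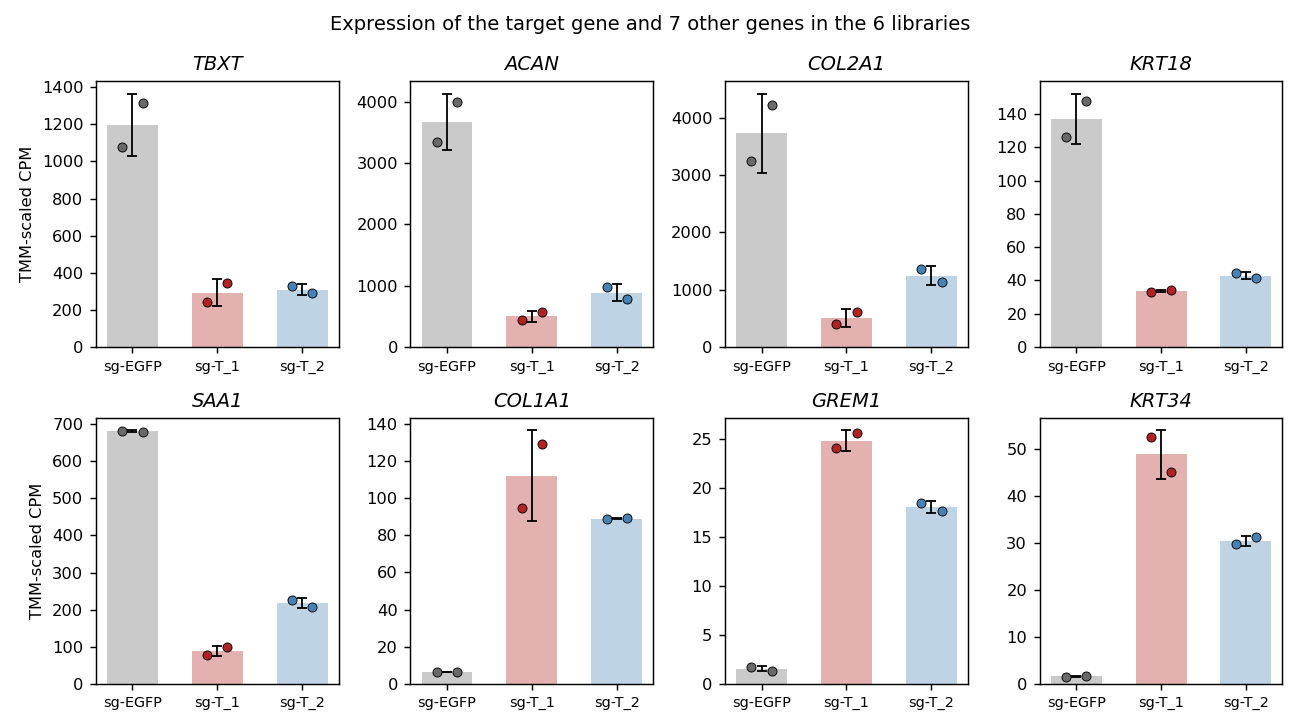
TMM-scaled CPM of TBXT and 7 other genes in the 3 groups, as bars for group means, error bars for the SD of 2 replicates and points for single libraries. TBXT stood at 1198 CPM with sg-EGFP against 293 and 309 CPM with the sg-T guides, and COL1A1, GREM1 and KRT34 were higher in all 4 sg-T libraries than in either control.

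Averaged over both guides, genes of cartilage matrix and of notochordal identity fell as lists (camera adjusted p = 4.1e-15 and 2.6e-12, and adjusted p = 0.135 and 0.192 with an estimated correlation). COL1A1, the alpha 1 chain of type I collagen, rose by 3.99 ± 0.16 (log2 fold change ± SE), from 6.31 CPM to 112 CPM with sg-T_1 and 89.1 CPM with sg-T_2. ACAN, the core protein of the proteoglycan aggrecan, changed by -2.47 ± 0.12, from 3671 CPM to 499 and 883 CPM. S phase and G2/M phase genes fell as lists and transcripts of the mitochondrial genome rose (camera adjusted p = 7.6e-17, 1.6e-14 and 7.2e-10, and adjusted p = 0.366 for each with an estimated correlation).

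The hair keratins KRT81 and KRT34 rose by 4.74 ± 0.19 and 4.64 ± 0.18. IGFBP5, which binds insulin-like growth factors, rose by 4.48 ± 0.27, and the homeobox factor DLX3 by 4.26 ± 0.24. PLEKHG4, a guanine nucleotide exchange factor, rose by 4.21 ± 0.28. ADAMTS14, a protease of the procollagen processing family, rose by 4.16 ± 0.23. GREM1, a secreted antagonist of bone morphogenetic proteins, rose by 3.81 ± 0.19, and the small GTPase RASD2 by 3.49 ± 0.20. Among lower genes, HPCAL4, a calcium sensor of the visinin family, changed by -3.23 ± 0.12, and TRIL, a partner of Toll-like receptor 4, by -3.12 ± 0.17. The sulfotransferase CHST4 changed by -3.08 ± 0.15, the receptors MRGPRX4 and MRGPRX3 by -2.95 ± 0.16 and -2.73 ± 0.12, and HAPLN1, the link protein of hyaluronan and aggrecan, by -2.92 ± 0.18. The aldo-keto reductase AKR1B10 changed by -2.61 ± 0.11, GSAP by -2.57 ± 0.17 and DDIT4L, an inhibitor of mTOR signalling, by -2.54 ± 0.11. PPIAP46, a pseudogene, had the lowest fold change under the naming rule, -3.32 ± 0.12. All 4 sg-T libraries lay on one side of both controls for each of the 20 genes under the naming rule, which the rule itself makes likely. The largest adjusted p among them, TRIL's, was 1.3e-08 (edgeR quasi-likelihood test, Benjamini-Hochberg). Several of these values may hold reads of a neighbour, or lack reads set aside as ambiguous or multimapping. The strand setting of the counting is not given in the sources used here. KRT81 overlaps KRT86 and has near-identical paralogs, PPIAP46 overlaps CYP11A1 on the other strand, and IGFBP5, PLEKHG4, GREM1, TRIL, CHST4, MRGPRX4, GSAP, DDIT4L and HAPLN1 also overlap other genes on the other strand.

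Over the 17250 genes tested, edgeR called 3030 higher and 3428 lower at an adjusted p under 0.05, of which 1016 and 982 changed at least 2-fold. Among all genes tested, called or not, all 4 sg-T libraries lay on one side of both controls in 52.3%. Chance gives 13.3% if all 6 libraries vary independently. Replicates that share an infection or preparation would raise that share, so the excess alone does not show an effect of targeting T. Without sg-EGFP replicate 2 the count of higher genes was 1923. Tested against a change of 1.5-fold, a setting chosen after seeing the data, 762 genes were higher and 1010 lower.

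Notochord and nucleus pulposus genes fell as a group: the camera test with a preset correlation of 0.01 gave adjusted p = 2.6e-12 for the list, and adjusted p = 0.192 with an estimated correlation. Of 15 tested members, TBXT left out, 10 were lower and 2 higher, with the same counts adjusted over the list alone, and the median log2 fold change was -1.13. The forkhead factor FOXA1 changed by -2.17 ± 0.13, SOX9, a driver of cartilage and notochord sheath programmes, by -1.84 ± 0.12, and the simple keratins KRT18, KRT8 and KRT19 by -1.85 ± 0.11, -1.74 ± 0.11 and -1.72 ± 0.12. KRT8 and KRT18 overlap on opposite strands. The signalling protein SHH changed by -1.25 ± 0.20 and the BMP antagonist NOG by -1.07 ± 0.11. BASP1 rose by 0.68 ± 0.12, CHRD by 0.40 ± 0.14, and CD24 stood at -0.02 ± 0.12. CHRD was no longer called without sg-EGFP replicate 1, at 0.25, without sg-T_2 replicate 1, at 0.38, scaled by library totals alone, at 0.36, or without a filter on low counts, at 0.38 (adjusted p = 0.275, 0.0873, 0.0524 and 0.0504).

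Cartilage matrix genes showed the lowest list median, -1.20. Of 17 tested members 13 were lower and 0 higher, with the same counts adjusted over the list alone (camera adjusted p = 4.1e-15, and adjusted p = 0.135 with an estimated correlation). Besides ACAN and HAPLN1, COL2A1, the collagen of cartilage, changed by -2.24 ± 0.15, from 3735 CPM with sg-EGFP to 503 and 1248 CPM with sg-T_1 and sg-T_2. COL9A3, a chain of the type IX collagen that coats these fibrils, changed by -2.37 ± 0.18. MATN3, a cartilage matrilin, stood at 0.10 ± 0.13.

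Proliferation genes fell almost throughout their lists. Of 43 S phase genes 39 were lower and 0 higher (40 lower adjusted over the list alone), with a median of -0.77, camera adjusted p = 7.6e-17, and adjusted p = 0.366 with an estimated correlation. The replication licensing factor CDC6 changed by -1.24 ± 0.12 and DTL, an adaptor of a ubiquitin ligase, by -1.27 ± 0.13. Of 54 G2/M phase genes 47 were lower and 0 higher (50 lower adjusted over the list alone), with a median of -0.62, camera adjusted p = 1.6e-14, and adjusted p = 0.366 with an estimated correlation. HMGB2 changed by -1.11 ± 0.11 and GAS2L3 by -1.21 ± 0.14, and the proliferation marker MKI67 by -0.91 ± 0.11. Direct p53 targets also fell, with 23 of 29 lower and 0 higher (25 lower adjusted over the list alone) and a median of -0.51. Camera gave adjusted p = 6.7e-09 for that list, and adjusted p = 0.135 with an estimated correlation. The phosphatase PPM1D changed by -1.20 ± 0.12 and the antiproliferative gene BTG2 by -1.04 ± 0.12, while CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at -0.20 ± 0.12 with adjusted p = 0.191 in the edgeR test.

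ERK pathway output genes were lower in 17 of 23 cases and higher in 3 (18 and 3 adjusted over the list alone), with a median of -0.77. Camera gave adjusted p = 1.3e-08, and adjusted p = 0.204 with an estimated correlation. The immediate early factor EGR1 changed by -3.03 ± 0.23, from 7.22 to 0.880 and 0.873 CPM, and the ephrin receptor EPHA4 by -1.31 ± 0.11, whereas MYC rose by 0.57 ± 0.12 and IER3 by 0.53 ± 0.12. Of 24 receptor tyrosine kinases and ligands reported in chordoma, 13 were lower and 1 higher, also when adjusted over the list alone, with a median of -0.48, camera adjusted p = 7.8e-05, and adjusted p = 0.182 with an estimated correlation. FGFR3 changed by -1.39 ± 0.12, its ligand FGF1 by -1.14 ± 0.11 and EGFR by -0.68 ± 0.11, while the insulin receptor INSR rose by 0.54 ± 0.13. Interferon-stimulated genes were lower in 11 of 26 cases and higher in 1, also when adjusted over the list alone, with a median of -0.47, camera adjusted p = 0.0248, and adjusted p = 0.829 with an estimated correlation. OAS1, a sensor of double-stranded RNA, changed by -1.50 ± 0.13, the exonuclease ISG20 by -1.31 ± 0.14, and STAT2 rose by 0.67 ± 0.12. The interferon list passed the threshold neither with the fry test (adjusted p = 0.132) nor with camera at a minimum of 1 CPM in 2 libraries (adjusted p = 0.0517). It also did not pass without sg-EGFP replicate 1, sg-T_1 replicate 2 or sg-T_2 replicate 1, where its median was -0.189, -0.265 and -0.392. The other 9 lists called over both guides passed with fry.

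Among genes of the mesenchymal state 12 of 24 were higher and 4 lower (13 and 4 adjusted over the list alone), with a median of 0.41, camera adjusted p = 0.0069, and adjusted p = 0.366 with an estimated correlation. The membrane protease MMP14 rose by 1.16 ± 0.12 and TGFBI, a matrix protein induced by TGF-beta, by 1.09 ± 0.13. CDH11, a cadherin of mesenchymal cells, changed by -1.41 ± 0.11 and the matrix protein TNC by -0.54 ± 0.12. Genes of the mitochondrial genome, listed as a sign of RNA make-up, were higher in 14 of 15 cases and lower in 0, also when adjusted over the list alone, with a median of 0.87. Camera gave adjusted p = 7.2e-10 there, and adjusted p = 0.366 with an estimated correlation. MT-CYB, cytochrome b, rose by 1.25 ± 0.13 and the ribosomal RNA MT-RNR2 by 1.09 ± 0.13. These genes took 3.42% ± 0.25 (SD, n = 2) of gene counts with sg-EGFP and 6.25% ± 0.78 over the 4 sg-T libraries, with p = 0.067 in a two-sided exact permutation test over 15 splits, the smallest p that design allows. Left out of the library sizes, a setting chosen after seeing the data, they changed the counts of called genes to 2973 higher and 3441 lower.

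**Figure D2:**
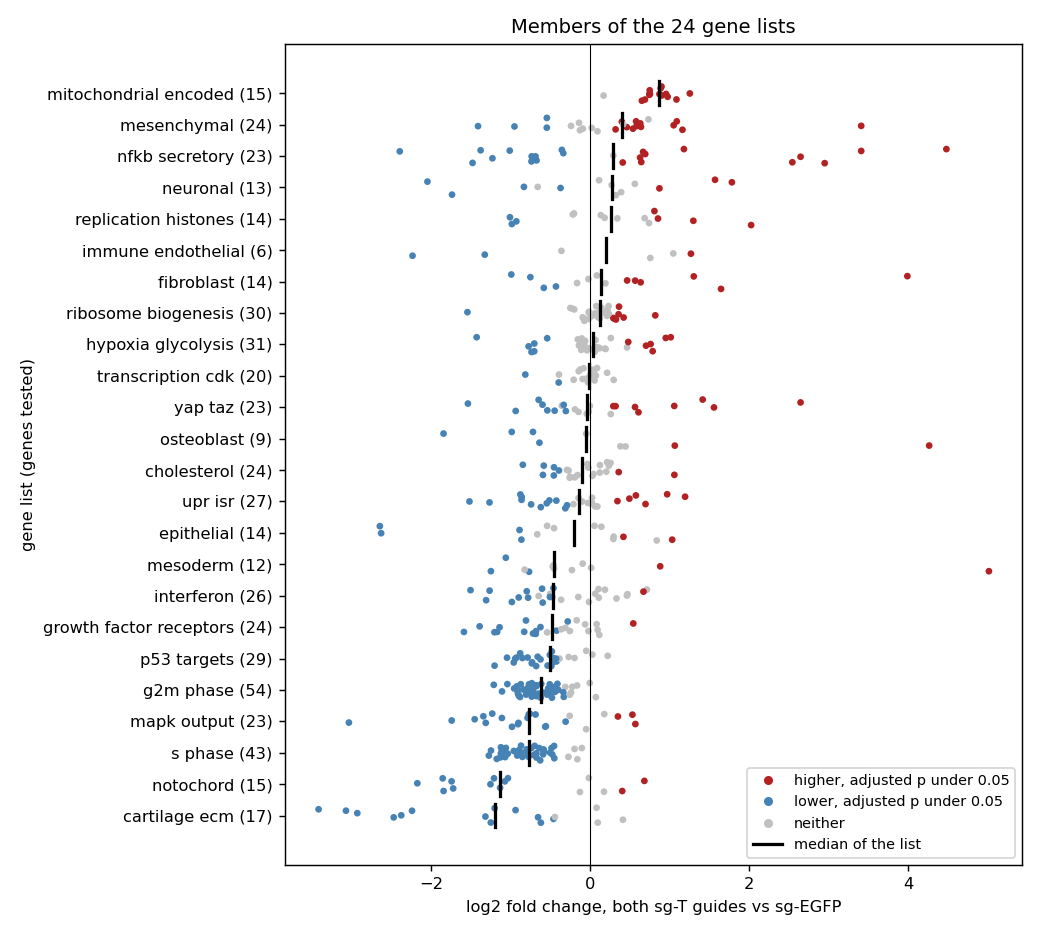
Log2 fold change of each tested member of the 24 gene lists (points, averaged over both sg-T guides against sg-EGFP), with the list median as a black line and the number of genes tested in brackets. The cartilage list has the lowest median, -1.20, and the mitochondrial genome the highest, 0.87.

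Averaged over both guides, the other 14 lists did not pass the camera threshold, and many held members that moved in opposite directions. Of 23 NF-kB targets and secreted factors of senescence, 11 were higher and 11 lower (camera adjusted p = 0.0628, and adjusted p = 0.366 with an estimated correlation). The list passed as higher with each guide alone (camera adjusted p = 0.0331 with sg-T_1 and 0.0096 with sg-T_2, and adjusted p = 0.309 and 0.201 with an estimated correlation) and with fry over both guides (adjusted p = 0.0142). IGFBP3, which binds insulin-like growth factors, rose by 2.64 ± 0.14 and the cytokine LIF by 2.54 ± 0.14, while the stromelysins MMP10 and MMP3 changed by -2.39 ± 0.12 and -1.23 ± 0.12. Both overlap WTAPP1, and the MMP3 call was lost when the 4 sg-T libraries were treated as 1 group (adjusted p = 0.13). Of 23 YAP and TAZ targets 8 were higher and 8 lower (adjusted p = 0.251): NT5E, the ecto-enzyme CD73, rose by 1.56 ± 0.13, and CTGF and the tissue factor F3 changed by -0.93 ± 0.11 and -1.53 ± 0.18. Of 12 mesoderm genes 2 were higher and 3 lower (adjusted p = 0.586), with TBX3 at 0.88 ± 0.12, the Notch ligand DLL1 at -1.25 ± 0.15 and FOXC2 at -1.06 ± 0.12. WNT5B, a Wnt ligand, had 2 counts over both sg-EGFP libraries and 125 over the 4 sg-T libraries, a ratio of 37.6 after scaling, with a 95% exact interval of 10.2 to 314 that covers counting error only. Of 31 hypoxia and glycolysis genes 6 were higher and 6 lower (adjusted p = 0.856), with the histone demethylase KDM3A at 1.01 ± 0.12 and the glucose transporters SLC2A1 at -1.43 ± 0.11 and SLC2A3 at 0.95 ± 0.14. Of 27 unfolded protein response and ATF4 genes 6 were higher and 12 lower (adjusted p = 0.141), with the cystine transporter SLC7A11 at 1.19 ± 0.13 and the pseudokinase TRIB3 at -1.52 ± 0.14.

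Of 24 cholesterol synthesis genes 2 were higher and 6 lower (adjusted p = 0.716), with the sterol isomerase EBP at 1.06 ± 0.13 and ACAT2 at -0.84 ± 0.12. Of 30 ribosome biogenesis genes 7 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.46), with RRP12 at 0.82 ± 0.12 and the lower gene, the nucleolar methyltransferase FBL, at -1.54 ± 0.11. Of 20 transcriptional kinase genes 0 were higher and 2 lower (adjusted p = 0.716), with the Mediator cyclin CCNC at -0.81 ± 0.12. Of 14 replication histone genes 4 were higher and 3 lower (adjusted p = 0.254), with HIST2H2BE at 2.02 ± 0.21 and HIST1H2AG at -0.93 ± 0.27, a call lost without sg-EGFP replicate 1, at -0.87.

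Of 14 fibroblast genes 6 were higher and 4 lower (camera adjusted p = 0.122 over both guides and 0.189 with sg-T_1). With sg-T_2 alone this list passed as higher (camera adjusted p = 0.0312, and adjusted p = 0.705 with an estimated correlation). Besides COL1A1, COL6A2 rose by 0.64 ± 0.12, while FBLN1 and COL6A3, a fibulin and a chain of type VI collagen, changed by -0.99 ± 0.11 and -0.58 ± 0.12. COL1A2, the partner chain of COL1A1 in type I collagen, stood at 0.497 CPM with sg-EGFP and 1.26 CPM over the 4 sg-T libraries. Of 9 osteoblast genes 2 were higher and 4 lower (adjusted p = 0.856), with DLX5 at 1.06 ± 0.14 and the phosphoprotein SPP1, osteopontin, at -1.84 ± 0.11. Of 13 neuronal genes 3 were higher and 4 lower (adjusted p = 0.856), with GAD1 at 1.78 ± 0.18 and CHGA at -1.73 ± 0.14. Of 6 leukocyte and endothelial genes 1 was higher and 2 lower (2 and 2 adjusted over the list alone, adjusted p = 0.716), with TEK at -2.23 ± 0.37 and PECAM1 at -1.32 ± 0.28. Of 14 epithelial genes 2 were higher and 4 lower (4 and 5 adjusted over the list alone, adjusted p = 0.586), with the claudin CLDN4 at 1.03 ± 0.16 and KRT7 at -0.89 ± 0.15. For the other lists that did not pass, the counts adjusted over the list alone were within 1 gene of those over all genes.

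With sg-T_1 alone, KRT34 rose by 4.98, KRT81 by 4.89, IGFBP5 by 4.57, ADAMTS14 by 4.43 and DLX3 by 4.33. The lowest values among called genes with a mean of at least 5 CPM were -3.51 for CHST4, -3.49 for PPIAP46, -3.41 for HPCAL4, -3.34 for MRGPRX4 and -3.30 for HAPLN1. The edgeR test called 2922 genes higher and 3157 lower in this comparison, and without sg-EGFP replicate 2 the higher genes numbered 1931. Camera called 11 of the 24 lists, the 10 called over both guides and the NF-kB list, and 0 with an estimated correlation (lowest adjusted p = 0.14).

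With sg-T_2 alone, KRT81 rose by 4.58, IGFBP5 by 4.38, KRT34 by 4.30, PLEKHG4 by 4.24 and DLX3 by 4.19. The lowest values among called genes with a mean of at least 5 CPM were -3.15 for PPIAP46, -3.05 for HPCAL4, -2.94 for TRIL, -2.65 for CHST4 and -2.57 for MRGPRX4. The edgeR test called 2095 genes higher and 2518 lower. Higher genes numbered 1348 without sg-EGFP replicate 1, and without sg-T_2 replicate 1 the counts were 1055 higher and 1367 lower, and without sg-T_2 replicate 2 they were 1226 and 1437. Camera called 11 lists, the NF-kB and fibroblast lists among them and the interferon list not (adjusted p = 0.0963), and 0 with an estimated correlation (lowest adjusted p = 0.188).

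The guides changed largely overlapping sets of genes. Both called 1951 genes higher, TBX3 and COL1A1 among them, and 2336 lower, ACAN and FOXA1 among them. Independent lists of these lengths would share 355 and 461 genes, and no gene was called in opposite directions. Across genes, which are not independent replicates, the fold changes of the guides had r = 0.929 and a covariance of 0.518. Simulated groups with no effect against the same controls gave a mean r of 0.478, a covariance of 0.0353 and a median of 0 shared calls. Unchanged groups give few calls by construction, so that 0 does not measure what shared controls add to the overlap. With 1 control library for each guide, r was 0.779 and the covariance 0.493. Part of the excess over independent lists may come from the shared controls. That part was not measured for the calls, since dividing the controls leaves each guide with 1 control library. Without sg-T_2 replicate 1 the shared calls numbered 1000 higher and 1320 lower, without sg-T_2 replicate 2 they were 1181 and 1384, and without sg-EGFP replicate 1 the higher ones numbered 1280.

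**Figure D3:**
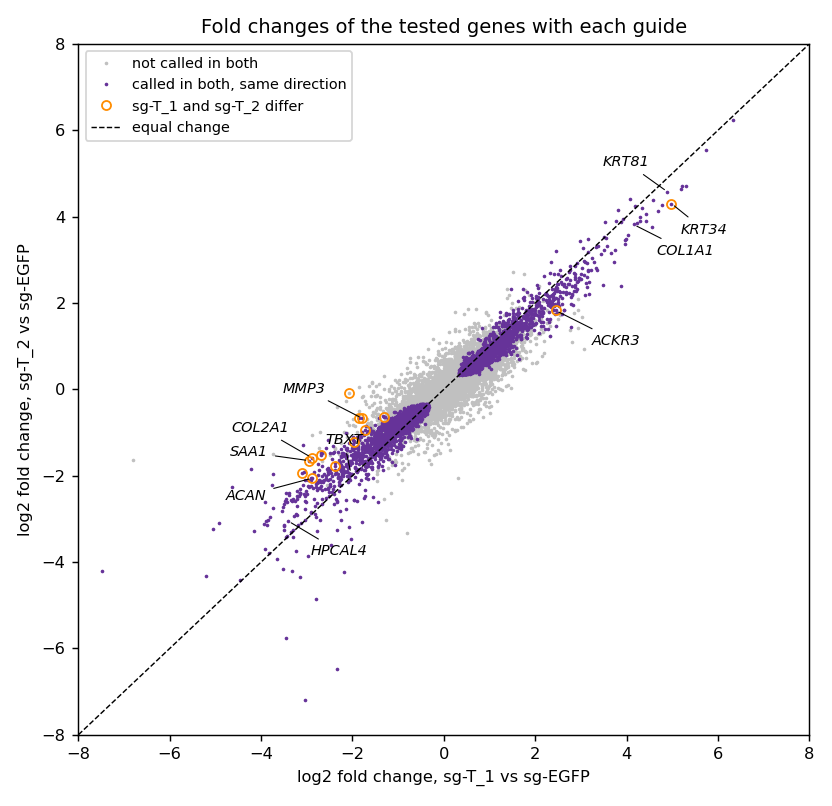
Log2 fold change against sg-EGFP of the 17250 tested genes with sg-T_1 (horizontal axis) and sg-T_2 (vertical axis). Purple points were called in the same direction with both guides, orange circles mark the 14 genes that differ between the guides, and the dashed line marks equal change. The correlation across genes is 0.929.

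Tested against each other, the guides differed in 14 genes, 12 of them lower with sg-T_1, and this count moved with the setting in both directions. SAA1, an acute-phase serum amyloid protein, stood at 682 CPM with sg-EGFP, 88.6 ± 14.3 CPM with sg-T_1 and 217 ± 13.7 CPM with sg-T_2, a log2 difference of -1.29 ± 0.14. MMP3 stood at 80.3, 23.4 and 50.3 CPM, a difference of -1.11 ± 0.14. COL2A1 differed by -1.31 ± 0.19 and ACAN by -0.82 ± 0.15. The interferon-induced membrane protein BST2 differed by -1.18 ± 0.21 and the glycine receptor subunit GLRA3 by -1.16 ± 0.25. SAA2 differed by -1.17 ± 0.24, and as a close paralog of SAA1 it may share reads with it or lack reads set aside. KRT34 and the chemokine receptor ACKR3 were higher with sg-T_1, by 0.68 ± 0.14 and 0.62 ± 0.14. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 2 genes higher and 12 lower with sg-T_1, where 698 of the 17250 genes had an unadjusted p under 0.05, fewer than the 5% that no difference would give. That low count is no evidence that the guides are alike, since p-values that run high or are correlated across genes also give it. The split was 33 higher and 177 lower without sg-T_1 replicate 2, 24 and 11 without sg-T_1 replicate 1, 1 and 6 without sg-EGFP replicate 1, 1 and 8 without sg-EGFP replicate 2, 0 and 6 without either sg-T_2 replicate, and 0 and 3 scaled by library totals alone. Across genes, the sg-T_1 replicates correlated less with each other (r = 0.9884) than each did with sg-T_2 replicate 1 (0.9912 and 0.9915), and they lay at 32.8 and -20.0 on the second principal component. Of the 14 genes, SAA1 and MMP3 passed the threshold under each of the 15 other settings run, with adjusted p of at most 3.5e-04 and 0.0354. Each of the others lost it under at least 3 settings, while its log2 difference kept its sign. The difference ran from -1.236 to -1.109 for GLRA3 and, with more spread, from 0.421 to 0.785 for ACKR3.

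Between the guides the cartilage list had a median log2 difference of -0.31 with 2 of 17 members lower (5 adjusted over the list alone), camera adjusted p = 1.1e-12, and adjusted p = 0.325 with an estimated correlation. The notochord list had a median of -0.10 with 0 members called over all genes and 6 lower adjusted over the list alone (camera adjusted p = 0.00178, and adjusted p = 0.673 with an estimated correlation). Camera also gave lower values with sg-T_1 for the S phase, G2/M phase, p53, interferon, ERK output and growth factor receptor lists, and with an estimated correlation none of the 24 lists passed, nor with fry.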

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

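The tests on the p53 targets, on depth by pairs of libraries and on fibroblast RNA were chosen after their values were seen; those on chromosome 6 (where only the fold change of DLL1 had been seen), on depth by thinning and on the share of unchanged cells were set out before.

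The following results drew attention because sg-T_1 and sg-T_2, both set against sg-EGFP, differed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 differences of sg-T_1 over sg-T_2 were 0.68 for KRT34, 0.62 for ACKR3, -1.31 for COL2A1, -1.29 for SAA1, -1.18 for BST2, -1.17 for SAA2, -1.16 for GLRA3, -0.82 for ACAN and -1.11 for MMP3. With the camera test at a preset correlation, median differences were -0.097 for the notochord list, -0.31 for cartilage matrix, -0.070 for S phase, -0.069 for G2/M phase, -0.065 for p53 targets, -0.13 for interferon-stimulated genes, -0.098 for ERK output and -0.078 for growth factor receptors, and none of these lists passed with an estimated correlation. Outside the gene counts, reads that matched no annotated feature made up 9.71% ± 1.41 (SD) of the reads listed in the 4 sg-T libraries and 7.64% ± 1.12 in the 2 sg-EGFP libraries, with every sg-T library above both controls (two-sided exact permutation p = 0.133 over 15 splits).

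Both sg-T guides were directed at a human gene and sg-EGFP has no target in the human genome, so, although editing was not measured in these data, the shared response could come from cutting rather than from loss of brachyury. A p53 response to cutting would raise p53 targets, but their median was -0.505, with 23 of 29 lower and 0 higher. This argues against a net rise of p53 targets at harvest. It cannot exclude a smaller rise masked by the fall of these genes, and whether p53 works in these cells was not tested. Loss of the chromosome arm beyond the cut would lower the genes between TBXT and the end of 6q: the median of the 31 tested there was -0.048 over both guides, -0.015 with sg-T_1 and -0.110 with sg-T_2, against -0.015, 0.009 and -0.017 for the 795 other tested genes of chromosome 6. Equally long runs of neighbouring genes lay as low in 35.3% of cases over both guides, 44.6% with sg-T_1 and 19.4% with sg-T_2. The limit for no loss set out before applied to the median and named no single guide. The median over both guides and that with sg-T_1 stayed within it, which argues against loss of the whole stretch in most cells. That with sg-T_2 lay just beyond it, so for sg-T_2 alone the test does not decide. Of the 9 genes called lower there, all but DLL1 lay at or before SMOC2, which starts at position 168441151. All 4 genes called higher lay beyond it. Before SMOC2, RPS6KA2 and FGFR1OP stood at 0.026 and 0.035 over both guides. This order along the chromosome was noticed after the values were seen. A shorter loss next to TBXT was not tested and stays open. Loss in some of the cells also stays open, since it would move a median little. Damage responses that bypass p53 and unintended targets of the guides were not tested, and loss of brachyury, the factor the design names, stays open as a hypothesis for the shared response.

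Changes were mostly smaller with sg-T_2 than with sg-T_1. Among 1998 genes called over both guides with at least a 2-fold change, 79.6% had the smaller change with sg-T_2. The median ratio was 0.865. With all libraries thinned to 17187785 counts it was 0.863, which decides nothing about depth, since thinning leaves fold changes as they are on average. Genes are not independent replicates, so the 79.6% is no test of a difference between the guides. Gene by gene, edgeR gave 698 of 17250 genes an unadjusted p under 0.05 between the guides, fewer than no difference would give. Beside 14 adjusted calls, so low a count means that p-values here run high or are correlated across genes. It is no evidence that the guides are alike. By pairs of libraries, sg-T_2 replicate 1, which with 25317631 counts was deeper than either sg-T_1 library, was compared first. Its median ratio was 0.894 and 0.834 against sg-T_1 replicates 1 and 2. The shallower sg-T_2 replicate 2 gave 0.905 and 0.841. Changes were thus smaller with the deeper sg-T_2 library too. These ratios also come from scaled fold changes, which depth leaves as they are on average, so the pairs decide nothing about depth either. A larger share of unchanged cells with sg-T_2 would scale all changes alike on the linear scale. There sg-T_2 showed a median 0.803 of the sg-T_1 change for higher genes and 0.916 for lower genes, a difference of 0.113 that ran from -0.017 to 0.205 over the 4 pairings of libraries, so such a mixture cannot be told apart from a gene-specific difference with 2 libraries per guide. TBXT itself showed 0.982 of the sg-T_1 change, and a difference between the guides in residual brachyury protein was not tested.

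COL1A1 rose from 6.31 to 101 CPM over the 4 sg-T libraries, which might reflect fibroblast cells or RNA. Fibroblasts would bring their other abundant transcripts too, but COL1A2, COL3A1, DCN and LUM together rose by 0.0155 of the COL1A1 rise, and COL3A1 and DCN stayed below 0.1 CPM in both the control and the sg-T means. This argues against fibroblasts as the source. A change of COL1A1 within the UM-Chor1 cells after T was targeted stays open as a hypothesis.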

How the results depend on the processing

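TBXT kept its direction and its call under every setting run, between -2.31 and -1.81 on the log2 scale over the 3 comparisons. Of 1913 alternative values for named genes and 169 for called lists none changed sign, and 104 and 15 lost the threshold; of 114 named-gene results against sg-EGFP, 9 lost it at least once (among them CHRD, DSP, ESAM, GNL3, HIST1H2AG, HIST1H2BJ and MMP3). The 2 settings chosen after seeing the data were the 1.5-fold test and leaving out the mitochondrial genome. Tested against a 1.5-fold change, by construction a stricter question, 762 genes were higher and 1010 lower over both guides, 843 and 1024 with sg-T_1, and 459 and 663 with sg-T_2. Of the 10 lists called, 0 passed with an estimated correlation, while 9 passed with fry and the interferon list did not. The correlation between the guides was 0.611 without a filter, which lets in genes with few counts, and 0.779 with 1 control library per guide. Leaving out a library gave 1923 to 3515 higher genes over both guides, lowest without sg-EGFP replicate 2, and 2452 to 4070 lower. For sg-T_1 it gave 1931 to 3162 higher genes, lowest without sg-EGFP replicate 2. For sg-T_2 it gave 1055 to 2587 higher and 1367 to 3138 lower genes, the higher count falling to 1348 without sg-EGFP replicate 1, and the counts to 1055 and 1367 without sg-T_2 replicate 1 and 1226 and 1437 without sg-T_2 replicate 2. Genes called in both guides ranged from 1000 to 2208 higher and 1320 to 2649 lower, with the same sg-T_2 libraries and, for higher genes (1280), sg-EGFP replicate 1 moving the count. The correlation ranged from 0.816 to 0.927. The comparison of sg-T_1 with sg-T_2, with 2 higher and 12 lower genes, moved most: 0 and 3 with library totals, 0 and 5 with at least 1 CPM in 2 libraries, 0 and 2 with only the 2 groups compared, 21 lower without a filter, and 4 higher with DESeq2, 1 with limma-voom and 1 without the mitochondrial genome. Leaving out a library there gave 0 to 33 higher and 6 to 177 lower, with 33 and 177 without sg-T_1 replicate 2, 24 higher without sg-T_1 replicate 1, 0 and 6 without either sg-T_2 replicate, 1 and 6 without sg-EGFP replicate 1, and 1 higher without sg-EGFP replicate 2. The cause was not tested where none is given. A lone replicate left in a group was assumed to vary like the other groups. With the replicate number as a block, the replicate block fit gave 3617 higher and 4026 lower genes over both guides and 19 and 61 between the guides; deviations of libraries with the same number correlated by 0.149, 0.065 and 0.048, so the numbers were not taken to pair the samples. On simulated data with 2 libraries per group 41.2% of changes of 0.5 on the log2 scale were recovered over both guides.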

Other observations

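Apart from the median of the genes beyond TBXT on chromosome 6, which was set out before, the tests and genes of this part were chosen after the data were seen.

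Of 2342 long non-coding genes tested, 497 were higher and 231 lower over both guides, and the others were not called. Of 13406 protein-coding genes 2238 were higher and 3075 lower. With library totals in place of TMM the counts were 392 and 233 for long non-coding genes and 1768 and 3323 for protein-coding genes. Pseudogenes showed 189 higher and 93 lower of 1066 tested. These counts came from the same edgeR test, were not compared with each other by a test, and stand beside the higher share of reads outside annotated features in the sg-T libraries, 9.71% against 7.64%.

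Beyond TBXT on 6q, 9 of the 31 genes tested were lower and 4 higher, with a median of -0.048. Over all 17250 genes tested, 3428 were lower and 3030 higher, and the counts on 6q were not tested against these. The 9 lower genes, DLL1 excepted, lay at or before SMOC2, and the 4 higher ones beyond it. DLL1, a Notch ligand, changed by -1.25 ± 0.15, with the smallest adjusted p of the 31 (9.9e-11). SMOC2, a matricellular calcium-binding protein, changed by -1.20 ± 0.19 and MPC1, a subunit of the mitochondrial pyruvate carrier, by -0.73 ± 0.13. RNASET2, a secreted ribonuclease, changed by -0.65 ± 0.12. WDR27 and ERMARD rose by 0.61 ± 0.12 and 0.74 ± 0.13. The adjusted p of the other 5 genes named here was at most 4.0e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

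The 10 most abundant genes took 7.78% ± 0.49 (SD) of gene counts with sg-EGFP and 11.6% ± 0.52 in the 4 sg-T libraries, with p = 0.067 in a two-sided exact permutation test over 15 splits, the smallest it can give. FN1, fibronectin, took 2.55% and 2.86% in the control libraries and 3.36% to 4.04% in the sg-T libraries.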
